A study of Oryza sativa Indica Group with 45 samples.

How the data were processed

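Affymetrix Rice Genome Arrays of the rice hybrid MRP5401 and its parents PMS80 (female, B parent) and PR319 (male, R parent) were analysed from the deposited table of processed values, with 57381 probe sets (123 of them controls) on 45 arrays. Per the labels, leaves and roots came from 14-day-old seedlings grown hydroponically in a culture room at 28 °C and from plants of 40 to 60 days, and flag leaves from plants of 90 days. RNA was extracted with Trizol and 5 µg were labelled as biotinylated cRNA. Groups were taken from the labels, which give 5 combinations of tissue and stage in 3 genotypes and 3 biological replicates in each of the 15 groups. The time of day of harvest, the scanner settings and the raw array files are not given in the sources used here.

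The deposited values are in intensity, on a linear scale, and per the submitters' processing notes they were made with GCRMA, of which no version is given. They were converted to log2, with values under 1 set to 1, and no further normalization was applied. The arrays were checked for identical pairs (0), for columns of other samples (0) and for correlation on the log2 scale, which was highest between 2 arrays at 0.997 and lowest within a group at 0.960. Probe sets with a mean log2 of 5 or more in at least 1 group and no control name were tested, which left 24130. With 3 arrays per group, the linear model had 30 residual degrees of freedom.

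Group means were fitted over all 45 arrays with limma 3.58.1 in R 4.3.3 with moderated t tests, and p-values were adjusted by the Benjamini-Hochberg method for each comparison, with a threshold of 0.05. The comparisons were the hybrid minus each parent, the hybrid minus the mid-parent (the mean of both parents in log2) and the R parent minus the B parent at each stage, 4 comparisons of tissue or age averaged over the genotypes, and the differences in hybrid minus mid-parent between the same tissues or ages. A probe set lay outside both parents where it passed against each of them in the same direction. In simulations of this design limma recovered 61 of 100 probe sets changed 2-fold and 93 of 100 changed 4-fold between groups of 3. It made 7 false calls among 24130. Camera called 0 of 31 unchanged lists beside a changed one. That sets no error rate for real lists, whose calls depend on the correlation used (4 of 56 held with an estimated one).

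Probe sets were paired with genes through the annotation of the array, which gives 1 gene for 22436 probe sets, several for 95 and none for 34850. Of the 17905 genes, 2442 carry a name. Only 3 of 30 gene lists fixed before the data were examined matched 5 genes or more by patterns in gene descriptions. Lists of NLR resistance genes, class III peroxidases and pentatricopeptide repeats were dropped. Once the annotation was seen, but before groups were compared, the other 27 were rewritten on gene names and 8 added. Of these 35 lists, 32 held at least 5 genes and were tested with camera at its preset correlation of 0.01, with the adjustment over the 32 lists of each comparison. Each member counted once, by its probe set with the highest mean.

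Genes are named by a rule fixed before the data were examined. Candidates were probe sets with exactly 1 gene and a descriptive name, without those marked as cross-hybridizing, taking the highest mean per gene. For each stage the 8 furthest above and the 8 furthest below both parents were taken, by the smaller of both differences, where all 3 hybrid arrays lay outside the range of the 6 parent arrays. For the parents the rule took 8 in each direction by the smallest difference over the 5 stages (4 were eligible upward), for each comparison of tissue or age 8 in each direction that moved alike in the 3 genotypes, and up to 4 members of each list past its test.

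The alternatives tried were quantile normalization, no level filter, array weights, the mid-parent on the linear scale, a fit of the compared stages alone, the replicate number as a block, an estimated correlation in the list tests and each array left out in turn. Chosen after seeing the data were the 3' index (4 control genes, 3' minus 5' signal) or the hybridization spike-ins as a covariate, 2 young leaf R parent arrays left out, R parent arrays left out, leaf-enriched probe sets left out, and the list tests with either covariate and with single arrays left out. Arrays with the same replicate number do not pair, since their residual correlations averaged between -0.114 and 0.0495 by stage. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.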

Results

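Transcript levels were measured in the indica rice hybrid MRP5401, its female parent PMS80 (B line) and its male parent PR319 (R line). The tissues were leaves and roots of hydroponic seedlings of 14 days and of plants of 40 to 60 days (mature leaf and mature root). Flag leaves, below the panicle, came from 90-day-old plants. Each of the 15 groups held 3 arrays, which the labels call biological replicates, so that the number of arrays limits the precision of every value. The median intensity of an array lay between 6.72 and 7.90, and the mean correlation of an array with the other arrays of its group between 0.960 and 0.991. Of 57381 probe sets, 24130 reached a mean log2 intensity of 5 in at least 1 group and were tested. Levels below are mean log2 intensities ± SD over 3 arrays, differences are on the log2 scale ± SE from limma, and a gene is said to rise, fall or change only where its adjusted p was under 0.05. A mean under 5 is close to background, so a difference with such a mean on its low side is given as a lower bound (at least, or more, without SE) with that mean set to 5, and means that are all under 5 have no order. Of the calls of each comparison, 1.98% to 12.6% had all compared means under 5 and so no order. Values under other settings are as fitted. The mid-parent is the mean of both parents on the log2 scale. Gene lists were tested with camera, and 56 of 448 list tests passed (27 upward and 29 downward, with 111 at an unadjusted p under 0.05). With an estimated correlation 4 of these held, namely photosynthesis, the Calvin cycle and photorespiration, chlorophyll synthesis and glutathione S-transferases, all in young roots of the hybrid against the mid-parent. The median over all tested probe sets was 0.20 in young leaves for the hybrid minus the R parent and 0.17 for the hybrid minus the mid-parent, -0.41 for leaf minus root at 14 days and -0.20 for mature minus young root. After quantile normalization these medians were 0.03, 0.03, -0.06 and -0.07, and all list medians are given relative to the median of all probe sets.

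**Figure D1:**
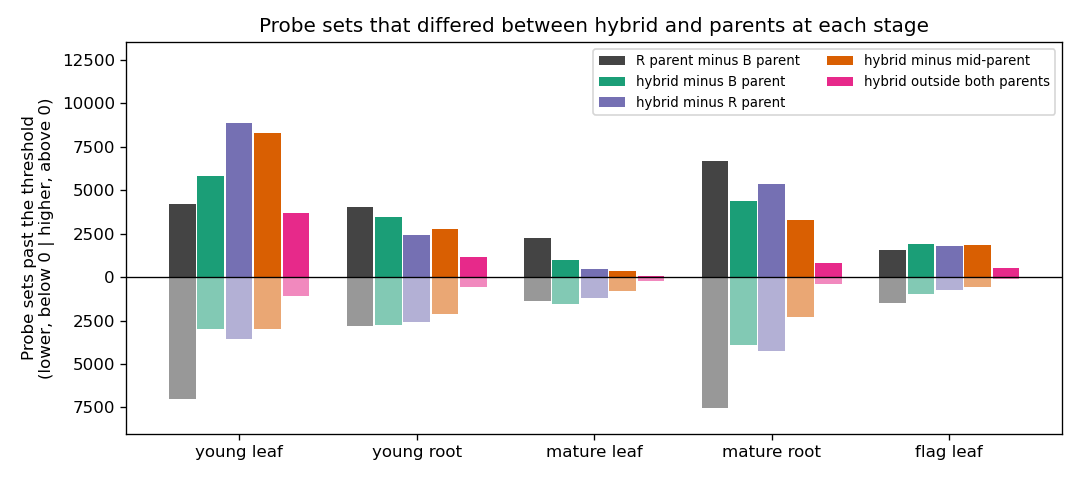
Numbers of probe sets past the threshold in each of 5 comparisons per tissue and stage, with higher calls in the full colour and lower calls in the paler one. Between the parents mature roots gave 14222 calls and young leaves 11180, an order that turned with the 3' index as a covariate (7511 and 10328) and without the level filter (17589 and 18508).

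In young leaves the hybrid was compared with each parent and with the mid-parent, to ask where its expression was not additive. The metal transporter gene OsZIP2 stood at 7.92 ± 0.28 in the hybrid, above 5.42 ± 0.32 in the B parent and 4.18 ± 1.69 in the R parent. The cellulose synthase-like gene CSLE1 was higher than in the B parent by 2.36 ± 0.42 and than in the R parent by 3.37 ± 0.42. EIL1B, of the ethylene signalling EIN3-like family, stood at 8.11 ± 0.13 against 5.85 ± 0.19 and 4.12 ± 1.48. In the other direction, the mannanase gene MAN1 was at 5.18 ± 0.83 in the hybrid against 7.76 ± 0.16 in the B parent and 9.64 ± 0.07 in the R parent. BURP3 and KRP6, a cyclin-dependent kinase inhibitor, were lower as well. TBL6 fell too (by at least 0.85 against the R parent), but its adjusted p was 0.0637 when only the young leaf arrays were fitted. Of the other genes furthest outside both parents, ABCG37, CAX1b, YSL13, PBZ1 and AT5 were higher and TUB8, RR1, BGLU28 and OsGT47D lower. All 9 of these calls were lost with the hybridization spike-ins as a covariate, where the smaller differences of ABCG37, CAX1b, YSL13, PBZ1 and AT5 were 1.21, 1.94, 1.54, 1.34 and 1.74 and those of TUB8, RR1, BGLU28 and OsGT47D -2.53, -2.06, -2.17 and -1.19. PBZ1 also lost its call without B parent replicate 2, hybrid replicate 1 or 3 or R parent replicate 3 (1.21 to 2.08), after quantile normalization (1.90), with array weights (1.79) and in a fit of young leaf arrays alone (adjusted p = 0.102), and AT5 without B parent replicate 2 or hybrid replicate 1 (1.34 to 1.77).

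In hybrid young leaves 4 gene lists passed camera downward against the mid-parent, although most members of each did not fall. Among 52 genes of cellulose and lignin synthesis, 18 fell and 12 rose (18 and 12 adjusted over the list alone, 1 call without order), but the list median, -0.36, was 0 with means under 5 set to 5. CSLA1 fell by at least 2.20, the lignin pathway ligase gene 4CL2 by at least 2.64 and the secondary wall cellulose synthase gene CESA4 by at least 1.20, and the laccase gene LAC4 averaged 7.85 in the B parent and under 5 in the hybrid and the R parent. For the wall synthesis list camera gave an adjusted p = 0.013 (0.652 with an estimated correlation). Of 22 expansins and other wall-loosening genes, 6 fell, 1 rose and 15 did not pass (6 and 1 adjusted over the list alone, 1 call without order), with EXPB4 at -2.32 ± 0.27, XTH8 at -2.02 ± 0.40 and EXPB3 at -1.97 ± 0.46, and the list median of -0.39 was also 0 with such means at 5. The wall-loosening list passed camera at adjusted p = 0.013 (0.652 with an estimated correlation). Of 16 chlorophyll synthesis genes, 7 fell, 1 rose and 8 did not pass (7 and 1 adjusted over the list alone), among them the protochlorophyllide reductase gene PORA at -1.48 ± 0.45 and PPOX1 at -1.44 ± 0.25, and the list median was -0.63. For the chlorophyll list camera gave an adjusted p = 0.00495 (0.652 with an estimated correlation). Of 20 aquaporins 5 fell, 2 rose and 13 did not pass (5 and 2 adjusted over the list alone), with PIP1-1 at -1.04 ± 0.24 and a list median of -0.42 (-0.18 with such means at 5). The aquaporin list passed camera at adjusted p = 0.0317 (0.652 with an estimated correlation). The wall synthesis, wall-loosening and aquaporin calls were lost after quantile normalization (adjusted p = 0.103, 0.103 and 0.109), all 4 were lost without the level filter (adjusted p = 0.0724 to 0.812), and the aquaporin call was also lost with the linear mid-parent (adjusted p = 0.0611) or without hybrid replicate 2 (adjusted p = 0.0677). The R parent arrays, part of the mid-parent, stood apart here, with a mean correlation within the group of 0.965 (the lowest of 15 groups). Their median intensity on the linear scale was 7.69 ± 0.29 against 6.87 ± 0.11 in the hybrid. Their array weights were 0.23 to 0.49, though the 4 lists passed without any 1 of these arrays.

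Across all tested probe sets of young leaves, limma called 8308 higher and 3014 lower in the hybrid than in the mid-parent, so that 73.4% of calls were higher, against 56.7% after quantile normalization. Against the R parent 8862 were higher and 3543 lower (71.4%, and 54.2% after quantile normalization), and against the B parent 5810 and 2972 (66.2%, and 54.5%). Above both parents stood 3700 probe sets and below both 1092 (77.2% above, and 56.4% after quantile normalization), where independent lists of these sizes would share 2134 and 436. At an unadjusted p under 0.05, 4534 stood above both and 1372 below both, against 120 and 118 in simulated groups without an effect. Part of any excess over independent lists may come from the hybrid arrays that both comparisons share, as 3 arrays cannot be parted into 2 sets of at least 2. The hybridization spike-ins of young leaf arrays averaged 10.89 ± 0.20 in the hybrid, 11.84 ± 0.62 in the B parent and 13.01 ± 0.41 in the R parent. With them as a covariate, 5862 probe sets differed from the mid-parent, 5541 from the R parent and 2310 from both. Fitting the young leaf arrays alone left 5758 against the B parent and 2904 outside both, and without the level filter 19137 differed from the mid-parent (44.0% higher) and 25300 from the R parent (35.9% higher).

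In young roots several of the named genes above both parents act in photosynthesis or chlorophyll synthesis. RCABP69, which encodes a chlorophyll a/b-binding protein, stood at 12.84 ± 0.44 in the hybrid against 10.52 ± 0.73 in the B parent and 10.17 ± 0.15 in the R parent, and LHCP, of the same family, was higher too. The magnesium chelatase subunit gene CHLH was at 9.79 ± 0.58 against 7.36 ± 0.76 and 5.85 ± 1.26, and PORA and the plastid aldolase gene ALDP were higher as well. The copper transporter gene COPT2 (by at least 5.18 and by 2.31 ± 0.49), BURP16 and the beta-glucosidase gene BGLU3 were also above both parents. Below both parents, the defence-related gene Pir7b was at 7.41 ± 0.69 against 10.52 ± 0.90 and 12.17 ± 0.09. The nonsymbiotic haemoglobin gene NSHB1, the ethylene synthesis gene ACS2, the ammonium transporter gene AMT1-1, GSTZ5, APR-like1, AC2 and WRKY76 were also below both. The WRKY76 call was lost without B parent replicate 3, where its smaller difference was -1.59.

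Against the mid-parent in young roots, 11 of 12 photosynthesis genes rose and none fell (11 adjusted over the list alone), with RCABP69 at 2.49 ± 0.17, LHCP at 2.27 ± 0.17 and petC at 2.02 ± 0.41. For the photosynthesis list camera gave an adjusted p = 7.19e-15 (0.00362 with an estimated correlation). When only young root arrays were fitted the adjusted p of petC was 0.0523. Of 9 genes of the Calvin cycle and photorespiration 7 rose (7 adjusted over the list alone), among them GDCSH at 1.73 or more and the Rubisco activase gene OsrcaA1 at 1.74 ± 0.16. The Calvin cycle list passed camera at adjusted p = 4.71e-06 (0.0254 with an estimated correlation). Of 16 chlorophyll synthesis genes 11 rose (11 adjusted over the list alone), with CHLH at 3.18 ± 0.34 and PORA at 1.86 or more. For the chlorophyll list camera gave an adjusted p = 1.28e-11 (0.0254 with an estimated correlation). The mean level of the photosynthesis list was 10.96 ± 0.30 in hybrid young roots, 9.37 ± 0.40 in the B parent and 9.67 ± 0.29 in the R parent. Group means of the root marker list lay between 7.15 and 7.91 in young roots and between 3.11 and 3.78 in leaves.

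In the hybrid's young roots 7 lists passed camera downward against the mid-parent, with most members past the threshold in 2 of them, phytoalexins and glutathione S-transferases. Of 11 diterpenoid phytoalexin genes, 8 fell and 3 did not pass (9 fell adjusted over the list alone), among them CPS2, KSL4 and CYP76M5, all of labdane-related diterpenoid synthesis, with means of 8.88, 9.07 and 5.68 in the R parent and under 5 in the hybrid and the B parent, so that their distance from the mid-parent has no bound. The phytoalexin list passed camera at adjusted p = 1.24e-06 (0.0773 with an estimated correlation). Of 6 glutathione S-transferase genes 4 fell (4 adjusted over the list alone), with GSTZ5 at -2.39 ± 0.22. For the glutathione S-transferase list camera gave an adjusted p = 0.00291 (0.0254 with an estimated correlation). Of 43 heat shock genes 12 fell and 4 rose (14 and 4 adjusted over the list alone, 1 call without order), including HSP17.4 by at least 1.82 and the heat shock factor gene HSF1 at -2.02 ± 0.26. The heat shock list passed camera at adjusted p = 0.0311 (0.416 with an estimated correlation). Of 14 abscisic acid and dehydration genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), with ABF2 at -1.30 ± 0.23, while LEA19 and the dehydrin gene RAB16D were under 5 in the hybrid and the R parent and the list median was -0.16 (-0.0045 with means under 5 set to 5). For the dehydration list camera gave an adjusted p = 0.0346 (adjusted p = 0.152 with an estimated correlation). Wall synthesis genes (10 of 52 fell and 3 rose, 10 and 3 adjusted over the list alone, 3 calls without order) included the laccase gene LAC19, which fell by at least 3.65. The wall synthesis list passed camera at adjusted p = 0.03 (adjusted p = 0.495 with an estimated correlation). Among 23 ribosomal protein genes 5 fell and 2 rose (9 and 2 adjusted over the list alone). For the ribosomal list camera gave an adjusted p = 0.017 (adjusted p = 0.565 with an estimated correlation). Among 17 genes of protein folding in the endoplasmic reticulum 4 fell (5 adjusted over the list alone), with a list median of -0.29 (-0.17 with such means at 5). The protein folding list passed camera at adjusted p = 0.0311 (adjusted p = 0.379 with an estimated correlation). The heat shock, dehydration and protein folding calls were lost after quantile normalization (adjusted p = 0.0528, 0.163 and 0.0528), the heat shock call with the spike-in covariate (adjusted p = 0.0604) and the protein folding call without hybrid replicate 3 (adjusted p = 0.0744).

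In young roots 2761 probe sets were higher and 2149 lower in the hybrid than in the mid-parent, 3447 and 2766 against the B parent, and 2417 and 2569 against the R parent. The linear mid-parent turned the share of higher calls against the mid-parent from 56.2% to 45.7%. Above both parents were 1137 probe sets and below both 587, where independent lists would share 345 and 294.5. Without hybrid replicate 2 the totals were 3209 against the mid-parent (4910 with it) and 1134 outside both (1724 with it). With array weights 8322 differed from the mid-parent, 9231 from the R parent and 3574 from both. After 3739 probe sets enriched in mature leaf over mature root were left out, 3151 differed from the mid-parent (42.3% higher) and 863 from both parents (40.3% above).

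Of 8 clock genes, 4 differed between the parents in young leaves and 5 in young roots, and 3 differed in both. The clock list passed camera between the parents in neither young leaves nor young roots (adjusted p = 0.694 and 0.695). PCL1, of the LUX family of clock components, stood in young leaves at a mean of 14.41 in the R parent, 11.17 in the hybrid and 6.18 in the B parent, and in young roots at 13.48, 11.75 and 5.95, with R parent minus B parent at 8.23 ± 0.29 and 7.53 ± 0.29. CCA1, a central clock gene named here after its values were seen, went the other way, at -4.52 ± 0.20 in young leaves and -4.44 ± 0.20 in young roots. The difference was 0.12 ± 0.29 for PCL1 and 0.14 ± 0.20 for CCA1 in mature leaves, -0.31 ± 0.29 and -0.05 ± 0.20 in flag leaves, and -1.97 ± 0.29 and 1.93 ± 0.20 in mature roots. Against the mid-parent, 6 of 8 clock genes rose in hybrid young leaves (6 adjusted over the list alone) with a list median of 0.64, including PRR95 at 2.12 ± 0.18, PRR1 at 1.75 ± 0.15 and PCL1 at 0.88 ± 0.25. Camera gave the list an adjusted p = 0.0164 (0.32 with an estimated correlation). In young roots 5 rose and 1 fell (6 and 1 adjusted over the list alone), with PRR95 at 2.18 ± 0.18, PCL1 at 2.04 ± 0.25 and PRR1 at 0.76 ± 0.15. The list passed camera here at adjusted p = 0.0117 (0.067 with an estimated correlation). Against the linear mid-parent the sign of PCL1 turned, to -2.24 in young leaves (limma adjusted p = 1.38e-07) and -0.74 in young roots (adjusted p = 0.0674). Both list calls were then lost (camera adjusted p = 0.287 and 0.255). With the spike-in covariate PCL1 in young leaves was 0.25 (adjusted p = 0.702). The labels give no time of day of harvest.

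**Figure D2:**
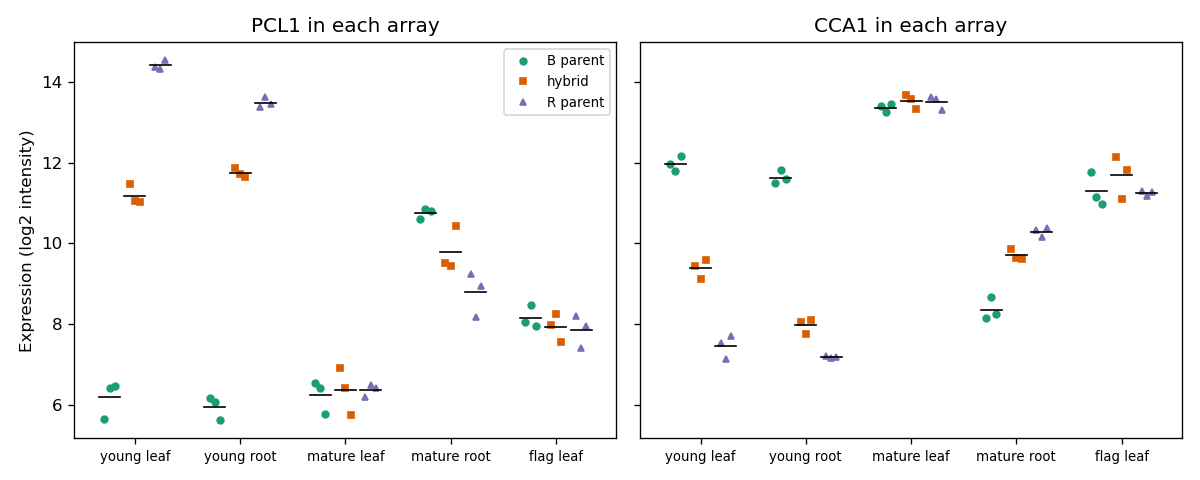
Log2 intensity of PCL1 and CCA1 on each array, by tissue, stage and genotype, with points for arrays and black lines for group means.

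In mature leaves the hybrid left both parents for few named genes. The dehydrin gene RAB16B was at 6.62 ± 0.12 in the hybrid against 5.17 ± 0.48 in the B parent and 3.88 ± 0.71 in the R parent, and CBF1 at 6.54 ± 0.28 against 4.87 ± 0.36 and 4.94 ± 0.27. Below both parents were TOP6B (6.47 ± 0.41 against 7.43 ± 0.22 and 7.41 ± 0.09), the phosphate transporter gene PHT1-8 (4.70 ± 0.40 against 6.56 ± 1.43 and 6.65 ± 0.55), WNK2 (4.25 ± 0.20 against 5.17 ± 0.58 and 5.90 ± 0.23) and MTR1. CDPMEK and CYP71Z7 were also called below both, at -0.98 and -2.74 for the smaller difference. GLU10 (all means under 5) and OsbZIP49 (hybrid and R parent under 5) were called too, but such means have no order. Without B parent replicate 1 or hybrid replicate 3 the call of CDPMEK was lost (adjusted p of up to 0.0851), that of OsbZIP49 without hybrid or R parent replicate 2 or 3 (adjusted p of up to 0.123), and that of CYP71Z7 without any of 7 of the 9 arrays, namely all but B parent replicates 2 and 3 (adjusted p of up to 0.165). All 3 were lost when mature leaf arrays were fitted alone (adjusted p = 0.052, 0.248 and 0.118), OsbZIP49 and CYP71Z7 after quantile normalization (0.0984 and 0.0731) and without the level filter (0.0531 and 0.0875), OsbZIP49 with the 3' index as a covariate (0.0619) and CYP71Z7 with the replicate block (0.0785). Abscisic acid and dehydration genes were the list that passed, with 1 of 14 past the threshold, RAB16B at 1.54 or more, and 2 adjusted over the list alone. For the dehydration list camera gave an adjusted p = 0.00352 (adjusted p = 0.0563 with an estimated correlation). Fitting the mature leaf arrays alone ended the calls of RAB16B (adjusted p = 0.0513), PHT1-8 (0.155), GLU10 (0.131) and WNK2 (0.0851) outside both parents, and the spike-in covariate ended those of WNK2 (-0.88) and MTR1 (-0.60).

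Against the mid-parent 352 probe sets of mature leaves were higher and 825 lower, which is 29.9% higher and 48.2% after quantile normalization. With the linear mid-parent 149 were higher and 1095 lower. Against the B parent 1004 were higher and 1566 lower, and against the R parent 468 and 1182 (28.4% higher, and 45.4% after quantile normalization). Above both parents were 36 and below both 202 (15.1% above, and 36.7% of 147 after quantile normalization), where independent lists would share 19.5 and 76.7. The totals against the mid-parent (1177) and outside both (238) were 608 and 141 without hybrid replicate 1 and 641 and 139 without hybrid replicate 2. Without R parent replicate 3 the total outside both was 140, and the total against the R parent (1650) was 1075 without that array and 1088 without hybrid replicate 2. Hybridization spike-ins averaged 12.48 ± 0.17 on B parent arrays, 11.36 ± 0.20 on hybrid and 11.49 ± 0.13 on R parent arrays of this tissue. With them as a covariate 523 differed from the mid-parent, 1041 from the B parent and 82 from both, while array weights gave 3608, 4625 and 977, and 4220 against the R parent.

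In mature roots the genes furthest above both parents included 2 expansins of wall loosening. These were EXPA5 and EXPA2, which stood at 9.07 ± 0.65 against 5.26 ± 1.07 in the B parent and 6.03 ± 0.37 in the R parent. CSLF2 was at 5.38 ± 0.17 with both parents under 5 (at least 0.38 above them), and the phytoene synthase gene PSY1 at 8.22 ± 0.28 against 3.38 ± 0.58 and 6.62 ± 0.26. GH3.4, of auxin conjugation, FTIP1 and ADIPOR2 were also above both. The aquaporin gene PIP2-7 was at 10.22 ± 0.22 against 3.36 ± 0.44 and 7.68 ± 0.69, a call lost without hybrid replicate 1 or R parent replicate 1 or 3 (2.24 to 2.45) and with the 3' index as a covariate (2.56). Below both parents, the glycolate oxidase gene GLO1 was at 3.46 ± 0.53 against 5.46 ± 0.78 and 6.17 ± 0.48, and G6PGH2, of the pentose phosphate pathway, was lower too. COPT2, GLN2, IAA13 and R1C-Prx were called below both as well, as were PRX74 and AMT1-2, whose means in the hybrid and 1 parent were under 5 and have no order. With the 3' index as a covariate the calls of COPT2 (-1.51), PRX74 (-1.96), GLN2 (-0.63), IAA13 (-0.64) and R1C-Prx (-1.13) were lost. The call of AMT1-2 was lost after quantile normalization (-0.74), without the level filter (adjusted p = 0.0789), in a fit of mature root arrays alone (0.0808), with the replicate block (0.0541) and without B parent replicate 1 or 2 or hybrid replicate 2 or 3 (up to 0.13), that of R1C-Prx without B parent replicate 3 (-0.58), with array weights (-0.73) and in a fit of mature root arrays alone (adjusted p = 0.0883), and that of GLN2 with the spike-in covariate (-0.99). None of 32 gene lists passed camera against the mid-parent (6 at an unadjusted p under 0.05).

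In mature roots 3277 probe sets were higher and 2272 lower than the mid-parent (59.1% higher, and 38.5% with the linear mid-parent), 4355 and 3927 than the B parent, and 5331 and 4280 than the R parent (2322 and 2695 of 2-fold or more). Above both parents were 819 and below both 394, where independent lists would share 962 and 696.5. The 3' index, the mean 3' minus 5' signal of 4 control genes and a sign of RNA integrity, was 1.59 ± 0.10 in the R parent, 3.71 ± 0.28 in the B parent and 3.63 ± 0.14 in the hybrid. With it as a covariate 3429 differed from the mid-parent, 2933 from the R parent and 477 from both, and with the spike-in covariate 6095 from the R parent.

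In flag leaves the genes furthest above both parents included 2 aquaporins. These were PIP2-2 and PIP1-1, which stood at 11.23 ± 0.52 against 9.62 ± 0.33 in the B parent and 9.64 ± 0.22 in the R parent. ABA8OX2, which encodes an enzyme that breaks down abscisic acid, was at 8.88 ± 0.10 against 7.10 ± 0.88 and 6.07 ± 0.20. The small heat shock protein gene hsp17.9, the phytoene synthase gene PSY3, PP2C68, Hox22 and RH2 were higher as well. The copper transporter gene COPT1 was below both parents, and SPL2, AGO17, YSL16, RH10, RPL11, ACA8 and VDAC1 were called below both as well.

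Without hybrid replicate 1 the flag leaf calls outside both parents of AGO17, Hox22, PP2C68, YSL16, RH10, RPL11, ACA8 and VDAC1 were lost, with Hox22 at 1.22. The calls of PP2C68 and YSL16 were also lost without B parent replicate 2 or 3 (adjusted p of up to 0.0974 and 0.0795) and that of RH2 without B parent replicate 1 (1.40). RH10 was lost without B parent replicate 1 or 3 or R parent replicate 2 (adjusted p of up to 0.137), RPL11 without R parent replicate 1 or 3 (0.249), ACA8 without B parent replicate 3, hybrid replicate 2 or any R parent array (0.24), and VDAC1 without hybrid replicate 3 or any R parent array (0.258). The 3' index as a covariate ended the calls of PSY3 (1.54), PP2C68 (1.27) and RH10 (-0.39), and fitting the flag leaf arrays alone those of hsp17.9, PSY3, RH2 and YSL16 (adjusted p = 0.0744, 0.067, 0.0558 and 0.0888). In that fit RPL11, ACA8 and VDAC1 were lost too (adjusted p = 0.0763, 0.0614 and 0.0608), ACA8 with the replicate block (0.0666), and ACA8 and VDAC1 also with the 3' index as a covariate (-0.47 and -0.49) and without the level filter (adjusted p = 0.0744 and 0.055), and VDAC1 after quantile normalization (0.0646).

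Against the mid-parent in flag leaves, 8 of 20 aquaporin genes rose and none fell (10 adjusted over the list alone), with PIP1-1 at 1.60 ± 0.24 and PIP1-3 at 1.52 ± 0.28. The aquaporin list passed camera at adjusted p = 0.000108 (adjusted p = 0.22 with an estimated correlation). Of 43 heat shock genes 15 rose and none fell (18 adjusted over the list alone), including hsp17.9 at 1.85 ± 0.31 and HSP17.4 at 1.51 or more, with a list median of 0.39 (0.24 with means under 5 set to 5). For the heat shock list camera gave an adjusted p = 0.000132 (adjusted p = 0.264 with an estimated correlation). Of 37 antioxidant genes 10 rose and 1 fell (19 and 2 adjusted over the list alone), with the glutaredoxin gene GRXC1 at 1.94 ± 0.30. The antioxidant list passed camera at adjusted p = 0.0346 (adjusted p = 0.264 with an estimated correlation). Of 23 ribosomal protein genes 8 fell and none rose (14 fell adjusted over the list alone), with 60SP0 at -0.71 ± 0.20 and RPL11 at -0.68 ± 0.16. For the ribosomal list camera gave an adjusted p = 4.15e-09 (adjusted p = 0.413 with an estimated correlation). The antioxidant call was lost without B parent replicate 1, hybrid replicate 2 or R parent replicate 2 (adjusted p of up to 0.157). Without hybrid replicate 1 the calls of HSP17.4 (adjusted p = 0.139), RPL11 (0.141) and 60SP0 (up to 0.287) were lost, that of 60SP0 without B parent replicate 2 as well. Fitting the flag leaf arrays alone ended the calls of HSP17.4, PIP1-3 and 60SP0 (adjusted p = 0.117, 0.0669 and 0.103). The 3' index moved in the same comparison, with 3.47 ± 0.42 in the hybrid (3.04 in replicate 1), 4.13 ± 0.25 in the B parent and 3.75 ± 0.19 in the R parent. With it as a covariate 1737 of the 2444 calls against the mid-parent were kept (71.1%), and these 4 lists passed.

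In flag leaves 1855 probe sets were higher and 589 lower than the mid-parent (75.9% higher, and 62.9% after quantile normalization), 1896 and 978 than the B parent (66.0%, and 54.2%), and 1813 and 764 than the R parent. Above both parents were 523 and below both 135 (79.5% above, and 64.8% after quantile normalization), where independent lists would share 142.5 and 31.0. Without hybrid replicate 1 the totals of 2444 against the mid-parent, 2874 against the B parent, 2577 against the R parent and 658 outside both were 1046, 1410, 1604 and 255, and without R parent replicate 2 the total against the R parent was 1674. Fitting flag leaf arrays alone gave 1116, 1766, 1541 and 288, and array weights 4167 against the R parent and 997 outside both.

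The parents were compared at each stage and across all 5. In young roots the R parent carried far more transcript of diterpenoid phytoalexin genes than the B parent. Of 11 such genes 10 rose (10 adjusted over the list alone), with CYP99A3 at 5.85 ± 0.50 and KSL7 at 4.66 or more. The phytoalexin list passed camera at adjusted p = 2.15e-10 (adjusted p = 0.0681 with an estimated correlation). Of 33 jasmonate genes 16 rose and 2 fell (17 and 2 adjusted over the list alone), among them OPR10 at 3.33 ± 0.43. For the jasmonate list camera gave an adjusted p = 0.00159 (adjusted p = 0.303 with an estimated correlation). Of 49 genes of the cell cycle and DNA replication 20 fell and 1 rose (23 and 1 adjusted over the list alone, 1 call without order), with MCM9 lower by at least 2.32 and the cyclin gene CYCD4-1 at -1.99 ± 0.39. The cell cycle list passed camera at adjusted p = 7.15e-05 (adjusted p = 0.405 with an estimated correlation). Of 6 histone genes 4 fell (4 adjusted over the list alone), with H2B.10 at -1.87 ± 0.24 and the centromeric histone gene CenH3 at -0.97 ± 0.30. For the histone list camera gave an adjusted p = 0.0182 (adjusted p = 0.345 with an estimated correlation). Of 13 gibberellin genes 6 rose (6 rose and 1 fell adjusted over the list alone), with KS1A at 1.02 or more and a list median of 0.64 (0.25 with means under 5 set to 5). The gibberellin list passed camera at adjusted p = 0.0448 (adjusted p = 0.124 with an estimated correlation). The histone call was lost without B parent replicate 1 (adjusted p = 0.0685) and that of CenH3 without B parent replicate 3 (adjusted p = 0.051). The gibberellin call was lost without B parent replicate 1 or 2 or R parent replicate 1 (adjusted p of up to 0.0725), after quantile normalization (0.0681) and with the 3' index or the spike-ins as a covariate (0.0909 and 0.0724). Markers of other tissue moved in this comparison too, with the shoot meristem list at 6.57 ± 0.34 in the R parent and 5.62 ± 0.22 in the B parent and root markers at 7.15 ± 0.14 and 7.78 ± 0.36, so that a different make-up of the root samples stays open for these lists. R parent replicate 1 stood apart (3' index 4.19, array weight 0.30), and without it the cell cycle and histone lists passed.

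In mature roots the R parent was higher in most aquaporin, jasmonate and pathogenesis-related genes and lower in most cell cycle genes of the lists. Of 20 aquaporin genes 17 rose and none fell (17 adjusted over the list alone), with the tonoplast gene TIP1-2 at 4.07 ± 0.30 and PIP2-7 at 2.68 or more. For the aquaporin list camera gave an adjusted p = 2.89e-05 (adjusted p = 0.113 with an estimated correlation). Of 33 jasmonate genes 20 rose and 2 fell (20 and 2 adjusted over the list alone), including OPR10 at 5.50 ± 0.43 and the allene oxide synthase gene AOS2 at 3.65 or more. The jasmonate list passed camera at adjusted p = 0.000738 (adjusted p = 0.234 with an estimated correlation). Of 20 pathogenesis-related genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), with the germin-like gene GER2 at 4.34 ± 0.59. For the pathogenesis-related list camera gave an adjusted p = 0.00111 (adjusted p = 0.234 with an estimated correlation). Metal transport genes (16 of 39 rose and 1 fell, 16 and 1 adjusted over the list alone) included YSL13 at 3.98 ± 0.55. The metal transport list passed camera at adjusted p = 0.0423 (adjusted p = 0.295 with an estimated correlation). Nitrogen genes (11 of 20 rose and 3 fell, 12 and 3 adjusted over the list alone, 1 call without order) included the glutamate dehydrogenase gene GDH2 at 2.83 ± 0.28 and AMT1-2 at 2.38 or more, with a list median of 1.33 (0.87 with means under 5 set to 5). For the nitrogen list camera gave an adjusted p = 0.0423 (adjusted p = 0.292 with an estimated correlation). Of 49 cell cycle genes 30 fell and 3 rose (31 and 3 adjusted over the list alone, 2 calls without order), with CYCB2-2 at -3.39 ± 0.36 and a list median of -0.99 (-0.63 with such means at 5). The cell cycle list passed camera at adjusted p = 0.000738 (adjusted p = 0.453 with an estimated correlation). Of 23 ribosomal protein genes 12 fell (12 adjusted over the list alone). For the ribosomal list camera gave an adjusted p = 0.0423 (adjusted p = 0.727 with an estimated correlation). The 3' index of the R parent, 1.59 ± 0.10 against 3.71 ± 0.28 in the B parent, differed in the same comparison as these lists, and with it as a covariate the calls of the jasmonate, metal transport and ribosomal lists (adjusted p = 0.0932 each) and the nitrogen list (0.147) were lost. The metal and nitrogen calls were lost without B or R parent replicate 3 (adjusted p of up to 0.0891 and 0.0609), and the ribosomal call without replicate 1 or 3 of either parent (0.143). Root markers (7.29 ± 0.27 in the R parent and 6.50 ± 0.22 in the B parent) and poly-A spike-ins (6.80 ± 0.43 and 9.57 ± 0.25) moved in this comparison too, so that sample make-up and processing stay open here.

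In flag leaves 3 of 6 histone genes were lower in the R parent (5 adjusted over the list alone), with H2B.10 at -3.11 ± 0.24, CenH3 at -1.06 ± 0.30 and H2B.6 at -0.70 ± 0.16. The histone list passed camera at adjusted p = 0.00288 (adjusted p = 0.353 with an estimated correlation). The call of CenH3 was lost without B parent replicate 2 or R parent replicate 2 or 3 (adjusted p of up to 0.107) and with array weights (-0.78), and when only flag leaf arrays were fitted the adjusted p was 0.136 for CenH3 and 0.0562 for H2B.6. In young and mature leaves 0 of 32 lists passed camera between the parents, with 3 and 2 at an unadjusted p under 0.05. The R parent minus the B parent gave 4182 higher and 6998 lower probe sets in young leaves (37.4% higher, and 48.9% after quantile normalization), 4058 and 2834 in young roots, 2276 and 1386 in mature leaves, 6673 and 7549 in mature roots (4688 and 4401 of 2-fold or more), and 1579 and 1486 in flag leaves (990 and 1032). The total of 14222 in mature roots was 7511 with the 3' index as a covariate, that of 6892 in young roots was 11406 with array weights, and that of 11180 in young leaves was 18508 without the level filter (61.3% higher).

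At all 5 stages the R parent was higher for 188 probe sets and lower for 254. Whether probe binding also differed was not tested. STLP5 was higher in the R parent by at least 2.47 at every stage, and CAD8C by at least 1.75. H2B.10 was lower at every stage, from -1.87 in young roots to -3.28 in mature leaves, as were MCM9 by at least 1.80 and EIL1B by at least 0.85. GWD3, of starch breakdown (-1.39 to -2.99), was lower too, as were BGLU9, KIN7C, ENR and HSP26.2 by at least 1.03, 0.87, 0.80 and 0.11, and SAP16 was higher (0.33 to 1.19). The sucrose synthase gene SUS6 was called higher at every stage, but both parents were under 5 in flag leaves. SUS6 lost its call at 1 or more stages in 25 of 45 single-array omissions (adjusted p of up to 0.231). HSP26.2 lost it without mature leaf B parent replicate 2 or 3 or R parent replicate 1 or 3, or young leaf B parent replicate 2 or 3 or R parent replicate 2 (adjusted p of up to 0.13). ENR lost it without mature leaf B parent replicate 1 or R parent replicate 3, or young root B parent replicate 1 or 3 or R parent replicate 2 or 3 (0.112), and SAP16 without mature root replicate 1 or 2 of either parent (0.125) and with the replicate block (0.055). BGLU9 lost it without young root B parent replicate 2 or R parent replicate 2 or 3 (0.141), and KIN7C without young root B parent replicate 1 or R parent replicate 2 or 3 (0.0723). GWD3 lost it without young root R parent replicate 1 (adjusted p = 0.0699). SUS6 and SAP16 also lost it after quantile normalization (adjusted p = 0.116 and 0.477) and with the 3' index (0.135 and 0.219) or the spike-ins (0.0865 and 0.0637) as a covariate. BGLU9 lost it with the 3' index (-0.46), ENR (LOC4345286) with the 3' index (-1.23) or the spike-ins (-1.17), and HSP26.2 with the spike-ins (-0.61). Without 2 young leaf R parent arrays SUS6, SAP16, HSP26.2 and GWD3 lost it (adjusted p = 0.0526, 0.114, 0.0827 and 0.0566), and without the level filter SUS6, ENR and HSP26.2 (0.105, 0.0513 and 0.0548). For these 442 probe sets the hybrid lay between its parents in 77.2% in young leaves, 91.4% in young roots, 97.5% in mature leaves, 90.3% in mature roots and 94.1% in flag leaves.

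Leaves and roots of the seedlings were compared over 9 arrays each. The aquaporin gene PIP2-7 averaged 14.56 ± 0.29 in leaves and 5.12 ± 2.24 in roots, the chalcone synthase gene CHS1 12.98 ± 1.13 and 5.65 ± 1.72, and the chloroplast regulator gene GLK2 12.92 ± 0.74 and under 5. In roots the silicon efflux transporter gene Lsi2 averaged 13.15 ± 0.11, the alcohol dehydrogenase gene Adh2 13.44 ± 0.36 and the phosphate transport gene PHO1-2 13.32 ± 0.31, at least 8.15, 8.44 and 8.32 above leaves, where all 3 were under 5. Pi21, GER5, GRXC1, HAK17 and GDCSH were also much higher in leaves (each by at least 7.03), and GER4, MT-1-4b, TIP2-1, OsCASPL1U3 and RAA1 in roots (each by at least 6.42). All 12 photosynthesis genes were higher in leaves (12 adjusted over the list alone), with ndhM at 6.08 ± 0.13 and a list median of 3.46. For the photosynthesis list camera gave an adjusted p = 1.97e-08 (adjusted p = 0.0833 with an estimated correlation). So were 15 of 16 chlorophyll synthesis genes (15 adjusted over the list alone), with CHLH at 4.88 ± 0.23 and a list median of 3.33. The chlorophyll list passed camera at adjusted p = 7.21e-09 (adjusted p = 0.108 with an estimated correlation). Of 9 Calvin cycle and photorespiration genes 7 were higher and 2 lower (7 and 2 adjusted over the list alone), with OsrcaA1 at 4.30 ± 0.11 and a list median of 3.78. For the Calvin cycle list camera gave an adjusted p = 0.00385 (adjusted p = 0.247 with an estimated correlation). Of 13 starch genes 7 were higher and 2 lower (7 and 2 adjusted over the list alone, 1 call without order), with the starch synthase gene SSII-2 at 3.38 ± 0.22 and a list median of 1.26. The starch list passed camera at adjusted p = 0.0196 (adjusted p = 0.383 with an estimated correlation).

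Another 5 lists passed camera downward in seedling leaves against roots. Of 49 cell cycle genes 41 were lower and 5 higher (41 and 5 adjusted over the list alone, 1 call without order), with CYCB2-2 lower by at least 3.63 and a list median of -2.0 (-1.25 with means under 5 set to 5). For the cell cycle list camera gave an adjusted p = 0.000373 (adjusted p = 0.383 with an estimated correlation). Of 22 wall-loosening genes 20 were lower and 1 higher (20 and 1 adjusted over the list alone, 1 call without order), with EXPB6 lower by at least 4.43 and a list median of -2.60 (-1.11 with such means at 5). The wall-loosening list passed camera at adjusted p = 0.00115 (adjusted p = 0.311 with an estimated correlation). All 17 protein folding genes were called lower (17 adjusted over the list alone), but 2 had both means under 5 and so no order, with PDIL1-5 lower by at least 3.41 and a list median of -0.94. For the protein folding list camera gave an adjusted p = 0.00344 (adjusted p = 0.247 with an estimated correlation). Of 23 ribosomal protein genes 21 were lower and 2 higher (21 and 2 adjusted over the list alone), with RPL5A at -2.79 ± 0.14 and a list median of -1.18. The ribosomal list passed camera at adjusted p = 0.00126 (adjusted p = 0.625 with an estimated correlation). All 5 root marker genes were lower (5 adjusted over the list alone), among them NIP2-1 at -4.24 ± 0.15 and SHR1 and WOX11, lower by at least 2.12 and 0.97, with a list median of -3.66 (-1.99 with such means at 5). For the root marker list camera gave an adjusted p = 0.00385 (adjusted p = 0.184 with an estimated correlation). In all, 6778 probe sets were higher in leaves and 12844 lower (34.5% higher, and 46.4% after quantile normalization), and without the level filter 40204 differed (63.8% higher).

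Mature leaves were compared with those of the hydroponic seedlings over 9 arrays each, so growth conditions may differ with age. The transporter genes OsZIP8 and OsZIP5 rose from 5.70 ± 1.15 to 13.15 ± 0.29 and from under 5 to 11.46 ± 0.83, the starch synthase gene SSI from under 5 to 11.54 ± 0.15, and the nicotianamine aminotransferase gene NAAT1, of iron acquisition, from 7.65 ± 1.17 to 14.50 ± 0.15. The cytokinin oxidase gene CKX4, HSP18.6 and the MADS-box gene MADS18 rose by at least 5.53, 5.31 and 5.08, and OsPP2C48 by 5.12 ± 0.17. GER5 fell from 12.74 ± 0.51, BURP16 from 13.09 ± 1.34 and the laccase gene LAC7 from 12.47 ± 0.72 to under 5, and GRXC10, MS, OSE727A, JAZ10 and DREB1B each by at least 3.15. In all, 8063 probe sets rose and 7789 fell, and 9832 changed with the 3' index as a covariate. None of 32 lists passed camera (7 at an unadjusted p under 0.05).

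Flag leaves at 90 days were compared with mature leaves. MADS14, a MADS-box gene of the floral transition, stood at 11.44 ± 0.36 in flag leaves and under 5 in mature leaves, a rise of at least 6.44. Nramp1 and PNP2 rose by at least 3.58 and 4.09, wsl3 by 4.49 ± 0.17, and BBD1, CCS1, LOX9 and GYRA by 4.21 to 4.47. The nicotianamine synthase gene NAS3 fell from 12.57 ± 0.28 to under 5, OsZIP5 from 11.46 ± 0.83 to 5.00 ± 1.98 and the iron transporter gene VIT1.2 from 11.37 ± 0.55 to 5.55 ± 1.27, while LTP2-B, Pi21, MT2B and BURP2 fell by at least 5.29. Of 52 wall synthesis genes 29 fell and 3 rose (29 and 3 adjusted over the list alone), with 4CL2 at -5.84 ± 0.20 and the cellulose synthase genes CESA8 and CESA1 lower by at least 3.47 and 3.26, though 7 of these 32 calls had both means under 5 and the list median of -0.61 was 0 with such means at 5. The wall synthesis list passed camera at adjusted p = 0.00155 (adjusted p = 0.399 with an estimated correlation). Of 20 aquaporin genes 14 fell and 2 rose (14 and 2 adjusted over the list alone), with PIP1-1 at -3.50 ± 0.16. For the aquaporin list camera gave an adjusted p = 0.000241 (adjusted p = 0.263 with an estimated correlation). Of 31 sucrose and hexose genes 18 fell and 4 rose (18 and 4 adjusted over the list alone, 1 call without order), with the sugar transporter genes SWEET2B at -3.71 ± 0.15 and SUT1 lower by at least 3.29. The sucrose and hexose list passed camera at adjusted p = 0.0135 (adjusted p = 0.263 with an estimated correlation). Of 23 ribosomal protein genes 22 rose and 1 fell (22 and 1 adjusted over the list alone), with RPL18 at 2.34 ± 0.22. For the ribosomal list camera gave an adjusted p = 5.2e-08 (adjusted p = 0.399 with an estimated correlation). In all, 8007 probe sets rose and 7475 fell. The 3' index moved with this comparison (group means of 3.47 to 4.13 in flag leaves and 2.21 to 2.59 in mature leaves), and with it as a covariate 10405 of the 15482 calls were kept (67.2%). The 4 lists passed then too.

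Mature roots were compared with the hydroponic young roots, so growth conditions may differ with age here too. PDC1, a pyruvate decarboxylase gene of fermentation, stood at 14.22 ± 0.59 in mature roots, the alpha-amylase gene AMY1.3 at 10.70 ± 1.01 and the iron transporter gene IRT1 at 10.11 ± 0.78, at least 9.22, 5.70 and 5.11 above young roots, where all 3 were under 5. IRL1, PM1, the jasmonate repressor gene JAZ5 and a chitinase gene (LOC4351188) rose by at least 5.39, 5.91, 4.83 and 4.11, and HSP18.1 by 6.15 ± 0.40. All 8 genes named for their falls except BIPP2C1 belong to the plastid. The chlorophyll a/b-binding gene CAB2R went from 14.72 ± 0.69, the plastocyanin gene PETE from 13.92 ± 0.72 and LHCP from 12.24 ± 1.22 to under 5, and OsrcaA1, RCABP69, petC, ADI1 and BIPP2C1 fell by at least 5.02, with 1 other probe set of BIPP2C1 going the opposite way. Of 12 photosynthesis genes 11 fell (11 adjusted over the list alone), with a list median of -6.21 (-5.44 with means under 5 set to 5). The photosynthesis list passed camera at adjusted p = 1.2e-07 (0.107 with an estimated correlation). All 9 Calvin cycle and photorespiration genes fell (9 adjusted over the list alone), with a list median of -3.01 and GLO1 at -5.97 ± 0.15. For the Calvin cycle list camera gave an adjusted p = 0.000298 (0.146 with an estimated correlation).

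Among the lists higher in mature than in young roots, 22 of 33 jasmonate genes rose and 7 fell (22 and 7 adjusted over the list alone), with LOX9 at 5.28 ± 0.36. The jasmonate list passed camera at adjusted p = 0.00302 (adjusted p = 0.282 with an estimated correlation). Of 14 phosphate genes 9 rose and 3 fell (9 and 3 adjusted over the list alone, 1 call without order), with the phosphate sensor genes SPX2 at 5.43 ± 0.19 and SPX3 at 3.01 or more and a list median of 1.45 (0.71 with means under 5 set to 5). For the phosphate list camera gave an adjusted p = 0.0228 (adjusted p = 0.263 with an estimated correlation). Of 43 heat shock genes 27 rose and 13 fell (27 and 13 adjusted over the list alone, 1 call without order), with HSP17.4 at 5.44 ± 0.30 and a list median of 1.08 (0.65 with such means at 5). The heat shock list passed camera at adjusted p = 0.0084 (adjusted p = 0.342 with an estimated correlation). Calcium-dependent and CIPK kinase genes (19 of 38 rose and 12 fell, 19 and 12 adjusted over the list alone, 2 calls without order) included CPK9 at 2.87 or more, and protein phosphatase 2C genes (27 of 52 rose and 15 fell, 28 and 15 adjusted over the list alone) PP2C30 at 5.30 ± 0.19, with list medians of 0.45 and 0.63 (0.19 and 0.43 with such means at 5). Both lists passed camera at adjusted p = 0.0464 (adjusted p = 0.342 each with an estimated correlation). Of 23 ribosomal protein genes 22 fell (22 adjusted over the list alone), with RPL27 lower by at least 3.50 and a list median of -0.43. For the ribosomal list camera gave an adjusted p = 0.0117 (adjusted p = 0.585 with an estimated correlation). Of 49 cell cycle genes 31 fell and 4 rose (31 and 4 adjusted over the list alone, 1 call without order), with CYCD5-1 lower by at least 2.20 and a list median of -0.45. The cell cycle list passed camera at adjusted p = 0.0464 (adjusted p = 0.585 with an estimated correlation). The kinase, phosphatase and cell cycle calls were lost in 7, 7 and 8 of 18 single-array omissions (adjusted p of up to 0.0597, 0.0569 and 0.0622). For kinases and phosphatases these were mature root B parent replicate 2, hybrid replicates 1 and 2 and R parent replicate 1, and young root hybrid replicate 1 and R parent replicates 2 and 3. For the cell cycle they were mature root B parent replicate 2, hybrid replicate 2 and R parent replicate 1, and young root B parent replicate 1, hybrid replicates 1 and 3 and R parent replicates 1 and 2. All 3 calls were also lost with the 3' index as a covariate (adjusted p = 0.0502 each) and with the replicate block (up to 0.0525). After quantile normalization the kinase and cell cycle calls were lost (adjusted p = 0.0651 and 0.104), and with the spike-ins as a covariate the phosphatase and cell cycle calls (0.062 and 0.0731). In all, 7540 probe sets rose and 11075 fell.

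**Figure D3:**
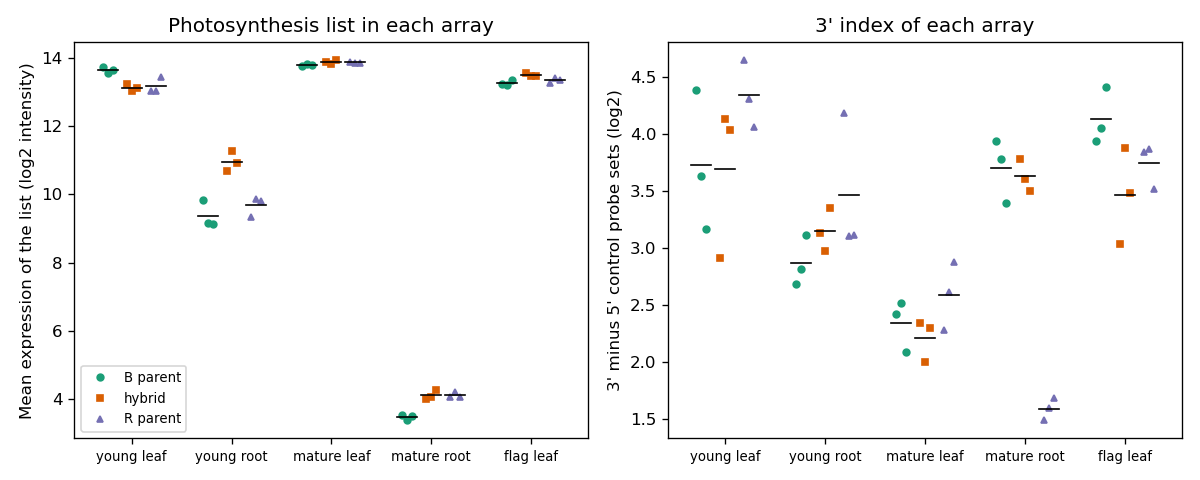
Mean log2 intensity of the photosynthesis list and the 3' index, in log2 units, on each array by tissue, stage and genotype, with points for arrays and black lines for group means.

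Whether the hybrid's distance from the mid-parent differed between tissues and stages was tested directly. It differed between young leaf and young root for 9889 probe sets, of which 6811 were higher in leaf (68.9%, and 53.8% after quantile normalization), and between mature and young leaf for 8798, of which 2007 were higher in mature leaf (22.8%, and 43.8%). Between flag leaf and mature leaf it differed for 1028 (904 higher in flag leaf, 87.9%, and 64.7% of 498 after quantile normalization), and between mature and young root for 5141 (2680 higher and 2461 lower, but 2350 and 2949 with the linear mid-parent, and 1615 and 1762 of 2-fold or more). The total of 1028 was 541 without flag leaf hybrid replicate 1, 530 and 602 without mature leaf hybrid replicates 1 and 2, and 3017 with array weights. The copper transporter gene COPT2 was higher than the mid-parent in young roots by at least 3.74 and lower in mature roots by at least 1.18.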

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

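All tests of explanations and all counts of other splits in this part were chosen after the results were seen, while the tests of differences between stages were planned. By direct tests the hybrid's distance from the mid-parent differed between young leaf and young root in 9889 probe sets. Between mature and young leaf it did in 8798, between flag and mature leaf in 1028, and between mature and young root in 5141. For the genes named in the report at a stage, 70 pairs of gene and stage (COPT2 at 2 stages) also had a distance there that differed from the mean over the other 4 stages, by the log2 amounts that follow. These genes were chosen for their values at that stage, so these differences are in large part set by the choice and say nothing of how stage-specific the genes are. Where means lie under 5, close to background, the amounts are not exact (as for GLU10, OsbZIP49, PRX74 and AMT1-2). In young leaf these were ABCG37 3.39, CAX1b 3.19, OsZIP2 3.43, CSLE1 2.69, YSL13 3.37, EIL1B 1.64, PBZ1 3.41, AT5 4.16, BURP3 -3.36, TBL6 -3.60, KRP6 -2.50, TUB8 -2.78, MAN1 -3.36, RR1 -2.38, BGLU28 -2.54 and OsGT47D -2.16. For young root the amounts were PORA 2.97, ALDP 2.03, CHLH 3.01, RCABP69 2.41, COPT2 4.27, BURP16 2.34, LHCP 2.16, BGLU3 2.44, Pir7b -3.73, NSHB1 -2.59, WRKY76 -2.99, GSTZ5 -2.34, APR-like1 -2.48, ACS2 -3.18, AC2 -1.55 and AMT1-1 -1.63. Mature leaf gave CBF1 2.30, RAB16B 2.00, CYP71Z7 -2.80, PHT1-8 -1.93, GLU10 -1.26, OsbZIP49 -1.61, TOP6B -1.02, WNK2 -1.34 and MTR1 -1.05. In mature root the differences were EXPA2 3.94, PIP2-7 4.28, EXPA5 3.05, CSLF2 2.66, FTIP1 2.32, GH3.4 2.00, ADIPOR2 1.82, PSY1 3.25, GLO1 -2.55, COPT2 -3.30, PRX74 -1.74, GLN2 -1.69, G6PGH2 -1.89, IAA13 -1.59, R1C-Prx -1.08 and AMT1-2 -2.22. Flag leaf values were PSY3 2.55, PP2C68 2.28, RH2 2.71, ABA8OX2 2.14, hsp17.9 1.94, PIP1-1 1.68, Hox22 1.50, PIP2-2 1.68, SPL2 -1.34, RH10 -0.80, AGO17 -1.28, YSL16 -1.41 and COPT1 -1.47.

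In young roots the hybrid stood above both parents for photosynthesis genes. Leaf tissue carried into the root samples stays open only as a part of the cause. The photosynthesis list would need a leaf share of 28.5%, and 8.82% of 1066 probe sets abundant in leaves lay more than 2 log2 units below the level that share implies, but the parents' young roots, each with its own implied share, gave 12.3% and 7.96%, so the value does not decide. Normalization between arrays does not account for it, since 11 of 12 genes were past the threshold upward after quantile normalization. A difference between the genotypes in root greening under light stays open and was not tested.

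PCL1, CCA1 and PRR1 differed between the parents in both young leaf and young root (3 of 8 clock genes), and the clock list passed camera in neither. Harvest at another time of day cannot be told apart from genotype, since the labels give no time, and these 3 genes went the same way in both tissues. A parental difference of these 3 genes that is as large at every stage is argued against by their median absolute differences. These were at most 0.31 in mature and flag leaf, against 4.52 in young leaf, 4.44 in young root and 1.93 in mature root. Over all 8 clock genes this test, run first, was undecided. The medians of young leaf, young root, mature leaf, mature root and flag leaf were 0.64, 0.98, 0.20, 0.76 and 0.22. Over all genes they were 0.53, 0.35, 0.25, 0.74 and 0.21. Growth conditions or a genotype effect at some stages only stay open, untested.

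Of the 5 comparisons of the parents, mature root had the highest count, at 14222, against 11180 in young leaf, although without the level filter young leaf was higher (18508 and 17589). RNA quality stays open as a cause of this order, since with the 3' index as a covariate, which also moves with genotype here, mature root gave 7511 and young leaf 10328. It is not the whole cause of the differences themselves, given the hybrid, whose 3' index of 3.63 is near the 3.71 of the B parent while its median position between the parents (0 at the B parent, 1 at the R parent) was 0.479 over probe sets that differed by 2-fold or more. Normalization between arrays is argued against by the 14181 calls after quantile normalization (young leaf 11455). A genetic difference between the parents in older roots stays open as untested.

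For 3 arrays against 3, the 10 splits of the same arrays are too few for a share under 0.05, and the real split was the only 1 as large in each. The real and the highest other counts for the hybrid minus the B parent were 8782 and 735 in young leaf, 6213 and 64 in young root, 2570 and 157 in mature leaf, 8282 and 2281 in mature root, and 2874 and 243 in flag leaf. For the hybrid minus the R parent they were 12405 and 2220, 4986 and 156, 1650 and 23, 9611 and 564, and 2577 and 36 in the same order, and for the R parent minus the B parent 11180 and 2574, 6892 and 163, 3662 and 15, 14222 and 1096, and 3065 and 149.

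For the comparisons with 100 splits, chance can be excluded at a share under 0.05 for the hybrid minus the mid-parent in young leaf (3 splits as large, the real one included; real 11322, highest other 12562) and flag leaf (4; 2444 and 2786). The count of splits alone does not exclude it in young root (5; 4910 and 7262), mature leaf (6; 1177 and 3465) or mature root (15; 5549 and 12680), nor for calls outside both parents in young leaf (7; 4792 and 10248), young root (9; 1724 and 5511), mature leaf (11; 238 and 2730), mature root (23; 1213 and 10827) or flag leaf (7; 658 and 2175). Against the mid-parent, all other splits as large in these 3 tissues put 2 or more arrays of 1 parent in the place of the hybrid (4 of 4, 5 of 5 and 14 of 14), and outside both parents most did (5 of 6, 5 of 8, 9 of 10, 20 of 22 and 4 of 6 in the order given). Such splits carry the difference between the parents, a structure of the samples, so that chance stays undecided in these comparisons. The splits as large in young and flag leaf were also of this kind (2 of 2 and 3 of 3), so that the splits do not decide there either whether the hybrid left the mid-parent. Chance can be excluded for leaf minus root (1; 19622 and 18307), mature minus young leaf (1; 15852 and 9604), flag minus mature leaf (1; 15482 and 10112) and mature minus young root (1; 18615 and 12618). The same holds for the differences in hybrid minus mid-parent between young leaf and young root (1; 9889 and 8819), mature and young leaf (1; 8798 and 8135), flag and mature leaf (2; 1028 and 1210) and mature and young root (2; 5141 and 5707).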

How the results depend on the processing

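The alternatives chosen after seeing the data are listed with the processing, and the others were planned. A count is named below where it moved by over 1.5 times, and the cause was not tested unless stated. With 3 arrays per group, and probe sets under a mean log2 of 5 left out as close to background, small differences and weakly expressed genes are beyond these data.

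With the 3' index as a covariate, mature root calls were 7511 for the R parent minus the B parent, 2933 for the hybrid minus the R parent, 3429 against the mid-parent and 477 outside both, and mature minus young leaf gave 9832. With the spike-ins as a covariate, young leaf calls were 5541 against the R parent, 5862 against the mid-parent and 2310 outside both, mature leaf calls 1041 against the B parent, 523 against the mid-parent and 82 outside both, and mature root calls 6095 against the R parent. Array weights gave 9231 against the R parent, 11406 between the parents, 8322 against the mid-parent and 3574 outside both in young root, 4625, 4220, 3608 and 977 against the B parent, the R parent, the mid-parent and both in mature leaf, 4167 against the R parent and 997 outside both in flag leaf, and 3017 for flag against mature leaf in hybrid minus mid-parent. Fitting the compared stages alone, which leaves fewer arrays to estimate the spread, gave 5758 against the B parent and 2904 outside both in young leaf, and 1766, 1541, 1116 and 288 against the B parent, the R parent, the mid-parent and both in flag leaf. Without the level filter, where more probe sets are tested, young leaf gave 25300 against the R parent, 18508 between the parents and 19137 against the mid-parent, leaf minus root 40204, and the list tests 135 calls. Quantile normalization gave 147 outside both in mature leaf and 498 for flag against mature leaf in hybrid minus mid-parent. Without leaf-enriched probe sets, young root gave 3151 against the mid-parent and 863 outside both. An estimated correlation left 4 of 56 list calls.

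Single arrays left out gave, lowest and highest, in flag leaf 1410 and 2923 against the B parent, 1604 and 2675 against the R parent, 1046 and 2497 against the mid-parent and 255 and 703 outside both. The lows came without hybrid replicate 1. In mature leaf they were 1075 and 1694 against the R parent (low without R parent replicate 3, and 1088 without hybrid replicate 2), 608 and 1158 against the mid-parent and 139 and 226 outside both. The last 2 counts were 608 and 141 without hybrid replicate 1 and 641 and 139 without hybrid replicate 2, and 140 were outside both without R parent replicate 3. In young root they were 3209 and 4643 against the mid-parent and 1134 and 1573 outside both (lows without hybrid replicate 2). For flag against mature leaf in hybrid minus mid-parent they were 530 and 1150, with 530 and 602 without mature leaf hybrid replicates 1 and 2 and 541 without flag leaf hybrid replicate 1. Flag leaf hybrid minus R parent gave 1674 without R parent replicate 2. The list tests gave 53 to 60 calls. The other counts stayed within 1.5 times under each omission. Of 414 genes and list tests, 64 lost their call in 1 or more omissions and 0 reversed.

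PCL1 in the hybrid minus the mid-parent reversed with the linear mid-parent, to -2.24 in young leaf and -0.74 in young root, since on the linear scale the high parent sets the mean. Of the genes and lists refitted, the number that lost their call was 30 with the 3' index, 26 with the spike-ins, 34 with the compared stages alone, 21 without the level filter, 20 after quantile normalization, 5 with the linear mid-parent, 4 with array weights, 4 without 2 young leaf R parent arrays, 2 without leaf-enriched probe sets and 0 without R parent arrays (limma, camera). Of the 56 list calls, 47 held after quantile normalization, 52 without the level filter, 53 with the linear mid-parent, 48 with the 3' index and 52 with the spike-ins. With the replicate number as a replicate block, no count moved by over 1.5 times, 12 genes or lists lost their call, and the list tests gave 57 calls, with 53 of the 56 held.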
